A study of Mus musculus with 3 samples.

How the data were processed

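Droplet single-cell RNA sequencing of mouse gastruloids was analysed in 3 libraries, 1 per group: gastruloids at 96 h after aggregation, and at 120 h the cells sorted on GFP into those with a Wnt record made at 96 h (G) and those without it (R). Per the labels, the libraries were made with the 10x Genomics Single Cell 5' v2 workflow from poly(A) RNA, with an extra primer for an iRFP reporter. The submitters' processing notes name Cell Ranger 6.0.1 and the mm10 genome. The deposited matrices hold UMI counts per gene and cell barcode, as whole numbers with no normalisation. Each matrix lists 32290 features, of which 5 are reporter constructs. Every listed barcode had over 500 UMIs, the lowest holding 503, so empty droplets had been removed before deposition and the free RNA of each library was not measured from them.

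Cells with at least 1000 detected genes and under 10% mitochondrial UMIs were kept. The cells with the highest Scrublet scores (the scanpy implementation) were then removed as probable doublets, up to 0.8% for every 1000 barcodes of the library. This left 3139 of 3496 barcodes at 96 h, 2933 of 3168 in G and 2172 of 2361 in R. Their endogenous UMIs summed to 56574956, 72434828 and 31371250. With the reporter features counted in, the medians were 17584, 22551 and 12540 UMIs per cell. UMIs were summed per gene over the kept cells and scaled to CPM of the endogenous total, without the reporter features. No test or p-value was computed, since cells of 1 library are not replicates. Each CPM has an exact Poisson 95% interval, each ratio of CPM an exact conditional binomial 95% interval and each share of cells a Clopper-Pearson 95% interval, with a log-scale (Katz) interval for a ratio of shares. These intervals, and the limit of 3 counts used for a count of 0, cover counting error only and no difference between gastruloids, sorts or library preparations.

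Lists of cell type markers and of pathway genes were fixed before the data were examined, as were the comparisons and the rule for naming genes. A list member counted as measured with at least 30 UMIs over the 2 sums compared. It counted as higher or lower when its CPM ratio was at least 1.5-fold from 1 and its interval excluded 1. Each list also has the median log2 ratio of its measured members, with 0.5 UMIs added to each sum, and the percentile of that median among 10000 random lists of the same size matched on mean expression. The named genes of G against R are the 10 highest and 10 lowest by the end of the interval nearest to 1, among genes of at least 50 CPM in the higher library. For 120 h against 96 h they are the 8 highest and 8 lowest in both 120 h libraries, with the same minimum. The plan ranked these by the ratio and the calculation ranked them by the end of the interval nearest to 1. Ranking by the ratio gives the same 8 higher genes and Defa30 in place of Grsf1 among the lower genes. Within a class they are the 5 highest and 5 lowest of at least 100 CPM, for the iRFP split the 8 highest and 8 lowest, and for each list up to 4 members with the largest log2 ratio. Mitochondrial, ribosomal protein, Gm and Rik genes were left out of this choice, and 10 canonical genes (T, Sox2, Axin2, Nodal, Bmp4, Fgf8, Cdx2, Tbx6, Meox1 and Cdh1) were always followed. A few of the genes that the rule names are not reported here as single genes and were counted in their lists.

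For classes, the cells of all libraries were clustered together: log-normalised UMIs per 10000, 2000 variable genes without mitochondrial, ribosomal and reporter genes, 30 principal components, a shared-neighbour graph of 15 neighbours and the Leiden method at resolution 1, with no batch integration. The rule for naming clusters from the fixed markers was written after the files were opened. A cluster took a name when at least 3 markers of a list were 1.5-fold higher in it than in the other cells of its stage and its 10 leading genes held markers of that list. The suffix -like marks that a name rests on these markers alone, NMP standing for neuromesodermal progenitor and PSM for presomitic mesoderm. Clusters with fewer markers, with leading genes that pointed to another type or with a low UMI count stayed unnamed. Within a class, G and R were compared where each held at least 100 cells.

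The comparison planned for the iRFP reporter at 96 h, cells with at least 1 iRFP UMI against cells with none, could not be made, because all 3139 kept cells had at least 1 iRFP UMI and 3138 had at least 2. Cells of the top and bottom 25% by iRFP UMIs per 10000 endogenous UMIs were compared in its place, a split chosen after the reporter counts were seen. For it each cell was thinned to 5000 UMIs, which 3072 of the 3139 cells reached.

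The calculations were tested on simulated counts with known ratios at the depths of G and R. The counts were Poisson draws from the pooled profile of G and R, each gene drawn on its own. They hold no spread between gastruloids, sorts or library preparations and no joint change of list members. The rates below therefore check the calculation and are not error rates of G against R. Of 14236 genes, 95.4% of the intervals held the true ratio, 0.826% of the unchanged genes and 0% of those with at least 1000 UMIs were called, and 95.5% of the genes changed 2-fold were recovered. At a 1.25-fold change 1.52% were recovered. For 200 lists of 10 unchanged genes, 94% of the percentiles lay from 2.5 to 97.5.

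The alternatives were no cell filter, a stricter filter (2000 genes, 5% mitochondrial UMIs), doublets kept, median-of-ratios scaling over genes with at least 50 UMIs in every library, the mean of per-cell CPM, each cell thinned to 5000 UMIs, and for the lists no UMI minimum, a minimum of 200 UMIs and a 2-fold threshold. Clustering was repeated at resolutions 0.5 and 2, with 3000 variable genes, without the S and G2/M phase genes and with each library alone. Alternatives chosen after the data were seen were reporter UMIs counted in the total, leaving out 4 unnamed clusters, Scrublet removal at 4 times the rate, leaving out the deep cells (above 1.5 times the median UMI count of their library) of 2 clusters, clustering without the 1269 genes that differed between G and R within a class, and 2 wider iRFP splits (top and bottom 33% and 50%). Gene positions are those of GENCODE on GRCm38 (mm10). The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.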

Results

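Which cell types and which gene programmes separate cells that had Wnt activity at 96 h of gastruloid culture from cells that had not was asked in single-cell RNA sequencing of mouse gastruloids, grown from an E14tg2a line that carries a Wnt recorder. In such a line, Wnt signalling during a set window leaves a lasting fluorescent mark, so that the past signal of a cell can be read a day later. The data were 1 library of gastruloids at 96 h (3139 kept cells) and 2 libraries of cells sorted at 120 h, those with Wnt recorded at 96 h (G, 2933 kept cells) and those with none recorded (R, 2172 kept cells). No group has replicates, so every interval given is a 95% interval for counting error only, and no difference was tested. Depth was unequal, with medians of 17584, 22551 and 12540 UMIs and 4336, 5265 and 3833.5 genes per cell at 96 h, in G and in R. The share of each sorted fraction in the whole 120 h gastruloid is not given in the sources used here, so G and R were never pooled.

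Somite-like cells, marked by Meox1, Tcf15 and Uncx, made up 33.3% (31.4 to 35.4) of R and 16.5% (15.2 to 17.9) of G at 120 h, a share 2.02-fold (1.82 to 2.23) higher without a Wnt record. Neuromesodermal progenitor (NMP)-like cells, which express T and Nkx1-2 and feed the growing body axis, made up nearly the same share of each, 29.97% (28.3 to 31.7) of G and 27.03% (25.2 to 28.9) of R. Presomitic mesoderm (PSM)-like cells, marked by Tbx6 and Msgn1, made up 26.9% of G and 19.6% of R, 1.38-fold (1.24 to 1.53) more in G, which turned to 0.894-fold when each library was clustered alone. Endoderm-like cells with Sox17 and Trh counted 31 in R (1.43%) and 1 in G, and endothelial-like cells with Cldn5 and Kdr counted 21 in R (0.967%) and 0 of 2933 in G, at most 0.102%. A further 26.5% of G and 17.7% of R stayed unnamed, mostly 1 cluster led by Mesp1, Bmp2, Frzb and Lhx1 that held 690 cells of G (23.5%) and 325 of R (14.96%). These shares are those of sorted cells from libraries whose median depth differed 22551 to 12540 UMIs. Clustering without the genes that differed between G and R inside a class gave G to R ratios of 0.658 for somite-like, 1.44 for PSM-like and 1.12 for NMP-like cells. The shares themselves moved more: somite-like cells were 25.7% to 31.8% of G and 38.7% to 43.7% of R in 4 clusterings (each library alone, doublets kept, thinned and without those genes), and PSM-like cells 52.1% of G and 35.6% of R at resolution 0.5. Without the deep cells of 2 clusters, which may be doublets, somite-like cells fell to 11.9% of G and 22.2% of R.

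**Figure D1:**
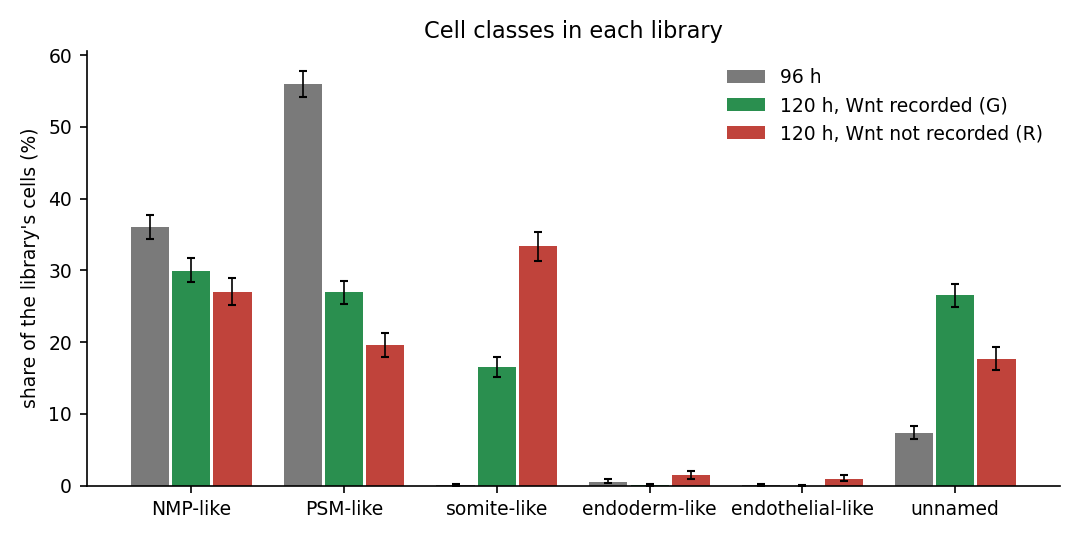
Share of each library's kept cells (%, vertical axis) by class for 96 h (grey), 120 h G (green) and 120 h R (red); bars are shares and error bars 95% Clopper-Pearson intervals. Somite-like cells made up 16.5% of G and 33.3% of R.

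The somite-like cells fell into 2 clusters with opposite shares. The cluster with Pax1 and Meox2 but without Mesp2 and Ripply2 among its markers held 28.1% of R and 8.83% of G, 3.18-fold more in R. The other, led by Ripply2, Mesp2, Pcdh8 and Cer1, genes that mark the forming somite boundary, held 7.71% of G and 5.25% of R, 1.47-fold (1.18 to 1.83) more in G.

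Which genes differed most between G and R at 120 h was asked over all cells of each library. By CPM the median log2 ratio of all genes was itself 0.09 for G over R, and 0.0003 with median-of-ratios scaling. Dll1 (ENSMUSG00000014773, chromosome 17, 15367354 to 15376872 on GRCm38), a Notch ligand that drives segmentation of the paraxial mesoderm, stood at 485 CPM in G and 304 CPM in R, 1.59-fold (1.56 to 1.63) higher. Of the other segmentation genes, Lfng, which modifies Notch, was 1.55-fold (1.44 to 1.66) higher, Dll3 1.43-fold (1.39 to 1.47), and the presomitic transcription factors Msgn1 1.44-fold (1.39 to 1.49) and Tbx6 1.42-fold (1.38 to 1.45). The ubiquitin ligase gene Rnf213 (132 against 86.0 CPM, 1.54-fold), the annexin gene Anxa11 (1.54-fold), the amino acid carrier gene Slc1a4 (1.49-fold), the Wnt antagonist gene Frzb (1.47-fold) and the semaphorin receptor gene Plxna2 (1.45-fold) completed the 10 highest of at least 50 CPM.

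Among genes of at least 50 CPM, the furthest below R was Igfbp5 (ENSMUSG00000026185, chromosome 1, 72857932 to 72874884), which encodes a secreted binder of insulin-like growth factors, at 34.2 CPM in G and 92.6 CPM in R, 2.71-fold (2.56 to 2.86) higher in R. Mest (ENSMUSG00000051855, chromosome 6, 30723547 to 30748465), an imprinted gene active in mesoderm, stood at 291 and 695 CPM, 2.39-fold (2.35 to 2.44) higher in R, and the metallothionein gene Mt1 at 22.2 and 50.8 CPM, 2.29-fold higher. The neurotrophic ligand gene Nrtn was at 0.587 (0.552 to 0.623) of its level in R, Hotairm1, a non-coding gene of the Hoxa cluster, at 0.617, the RNA-binding gene Hnrnpa0 at 0.690, Phlda1 at 0.689, Ngdn at 0.712, the ion pump subunit gene Fxyd6 at 0.717 and the cold-shock gene Ybx3 at 0.731.

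**Figure D2:**
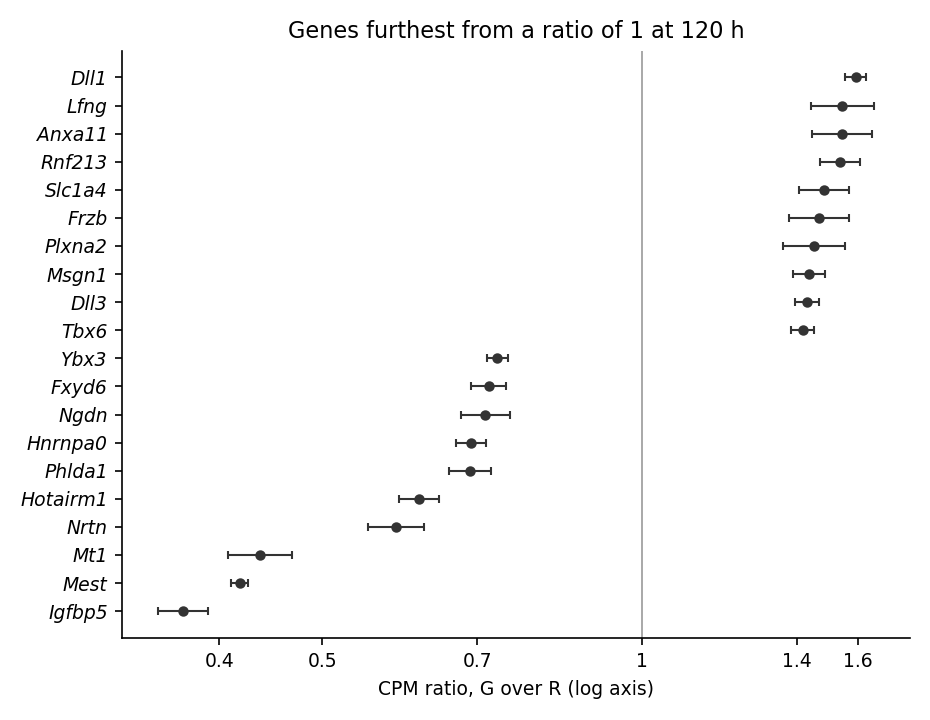
Ratio of CPM in G over R (log axis) for the 10 highest and 10 lowest genes by the interval end nearest to 1; points are ratios of summed UMIs and bars 95% counting intervals. Dll1 was 1.59-fold higher in G and Mest at 0.418 of its level in R.

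The Wnt targets lay higher in G as a group, with a median log2 ratio of 0.28 over 16 measured genes (percentile 100 among matched lists), although no member reached 1.5-fold. T, Wnt3a, Cdx4 and Sp8 of this list are also caudal progenitor markers, which were themselves higher in G (median 0.21, percentile 99.1). The Wnt median of G over R was not computed without these genes. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a feedback inhibitor used as a readout of Wnt, stood at 106 CPM in G and 74.9 CPM in R, 1.41-fold (1.35 to 1.48) higher. The ligand gene Wnt3a was 1.43-fold higher and the secreted antagonist genes Dkk1 and Notum 1.36-fold and 1.35-fold. T (brachyury; ENSMUSG00000062327, chromosome 17, 8434423 to 8442496), a Wnt target and mesoderm regulator, was 1.21-fold (1.17 to 1.26) higher, Fgf8 1.23-fold and the caudal homeobox gene Cdx2 1.19-fold. The epithelial cadherin gene Cdh1 was 1.43-fold (1.17 to 1.76) higher at a low level, 5.70 against 3.98 CPM. Sox2 was at 0.851 (0.775 to 0.936) of its level in R and Meox1 at 0.759 (0.741 to 0.778), while the intervals of Nodal (0.731, 0.528 to 1.02) and Bmp4 (1.06, 0.861 to 1.31) held 1.

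Presomitic markers had 2 of 8 members higher in G (Dll1 and Lfng) and none lower, median log2 ratio 0.51, and the Notch list 2 of 11 higher and Heyl lower (0.596), median 0.36. With median-of-ratios scaling no member of these 2 lists stayed above 1.5-fold. Somite markers turned the other way, with 5 of 11 lower, median −0.40, among them the sclerotome gene Pax1 (1.39 against 6.15 CPM, 0.227), Meox2 (0.288), Uncx (0.513) and the dermomyotome gene Pax3 (0.581). Without the deep cells of 2 clusters the somite median was −0.22. Weighting the clusters of G as in R, chosen after the values were seen, took the somite median to 0.005 (percentile 11.6) and the Notch median to 0.18 (percentile 99.2). Somite markers named the somite-like clusters and were not kept out of the clustering. The change of their median therefore cannot tell a difference in shares from a change of these genes in the cells. Caudal progenitor markers had a median of 0.21 with only Hes3 (0.574) lower, and streak markers 0.27 with Lhx1 (1.58, 1.34 to 1.86) higher and Wnt3 (0.443) lower. The neural list had 1 of 8 lower (Sox3, 0.656), median −0.18.

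Among the rarer cell types, endothelial markers had 4 of 6 lower, median −2.85. The tight junction gene Cldn5 had 1 UMI in G and 157 in R (0.00276, 6.94e-05 to 0.0156). Esam was at 0.0340, the VEGF receptor gene Kdr at 0.0464 and Plvap at 0.387. Endoderm markers had 4 of 9 lower, median −0.59, with the hormone gene Trh at 0.953 and 14.9 CPM (0.0641), Sox17 at 0.172 and Foxa2 at 0.217. This median was 0.12 with every cell thinned to 5000 UMIs. Thinning lowers the sums, so members with few UMIs can fall below the minimum for a measured gene. The thinned median may therefore rest on fewer members, and its sign does not show that equal depth reverses the difference. The same limit holds for the other thinned medians. The signal gene Shh of the notochord list was at 0.0722, Wt1 of the intermediate mesoderm list at 0.238, Krt7 of the trophoblast list at 0.296. Of the cranial mesoderm genes 3 of 6 were lower, among them Tbx1 (0.406) and Alx1 (0.450). In the lateral plate list Foxf1 was 1.57-fold higher, median 0.08 and −0.01 with median-of-ratios scaling. No measured member reached 1.5-fold in the pluripotency (6 of 11 measured; median 0.13, and −0.08 when thinned), cardiac (5 of 10; 0.05, and −0.04 with median-of-ratios scaling) and germ cell lists (4 of 6; −0.07, and 0.24 when thinned). The same held for the blood (2 of 8 measured), visceral endoderm (1 of 6) and neural crest (1 of 5) lists, which were barely measured.

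Of the remaining pathways, mesenchymal genes had 4 of 12 lower (Snai2 0.535, Prrx1 0.577, Twist1 0.586 and Cdh11 0.656), dissociation stress genes 2 of 11 (Fosb 0.615 and Fos 0.651; median −0.30), retinoic acid genes 2 of 10 (Rarb 0.603 and Dhrs3 0.662), and epithelial genes 2 of 10 (Crb3 0.609 and Krt18 0.663). With the clusters of G weighted as in R the stress median came to −0.04 (percentile 2.07). The matrix gene Col1a2 was at 0.277 and the BMP target Id4 at 0.580. The Nodal list had Lefty1 (2.74, 1.15 to 7.94) higher beside Lhx1, and 2 of 9 lower, Foxa2 among them, with a median of 0.03 that turned to −0.07 with median-of-ratios scaling. FGF targets (median 0.20), S phase genes (0.13), p53 targets (0.13) and Hox paralogs 1 to 4 (0.12), 10 to 13 (−0.20) had no member beyond 1.5-fold. Nor had Hox paralogs 5 to 9 (0.07, and −0.02 with median-of-ratios scaling), G2/M genes (0.02 and −0.07) and glycolysis genes (0.04 and −0.05).

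Whether G and R also differed inside a class was asked for the 3 classes with at least 100 cells in both. NMP-like cells (877 of G, 583 of R, counting the 120 h clusters of a class only) had more Axin2 (1.31-fold, 1.22 to 1.42) and Notum (1.3996-fold, 1.28 to 1.54) in G. Wnt targets had a median of 0.18 (percentile 99.9), with 0 of 16 members beyond 1.5-fold. Other lists stood out in this class too, such as presomitic markers higher (0.22, percentile 99.96) and somite markers lower (−0.38, percentile 0.02). Among genes of at least 100 CPM, as for the highest and lowest genes of each class, the highest were Slc1a4 (1.51-fold, 1.38 to 1.65), Notum, the adhesion gene Epcam (1.39-fold), the imprinted gene Peg3 (1.37-fold) and the tropomyosin gene Tpm1 (1.35-fold). The lowest were Ybx3 (0.659, 0.630 to 0.690), Hnrnpa0 (0.703), the mitochondrial tRNA ligase gene Lars2 (0.715), Sec61g (0.777) and Atp5md (0.785). Below that level, Cdh1 was 1.92-fold (1.47 to 2.54) higher and Meox1 at 0.525 (0.432 to 0.639). In PSM-like cells (789 and 422) Tbx6 (1.03, 0.993 to 1.08) was level, Axin2 was 1.18-fold (1.06 to 1.32) higher and the Wnt median was 0.03 (percentile 49.2). The transcription factor genes Sall1 (1.45-fold, 1.30 to 1.62) and Foxc2 (1.38-fold), the pyrimidine synthesis gene Cad (1.42-fold), Hist1h1b (1.31-fold) and the myosin gene Myh10 (1.29-fold) were the highest there, and Lars2 (0.672, 0.640 to 0.706), Ybx3 (0.677), Hnrnpa0 (0.740), Atp5k (0.768) and Cox7c (0.808) the lowest.

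Somite-like cells (485 of G, 724 of R) had 27 list members higher and 12 lower, in a class whose mix differed. The cluster led by Ripply2 and Mesp2 gave 226 of the 485 cells of G and 114 of the 724 of R. The boundary and oscillation genes Lfng (2.57-fold), Pcdh8 (2.55-fold, 2.36 to 2.77), Cer1 (2.39-fold), Mesp2 (2.23-fold) and Dll1 (2.02-fold, 1.94 to 2.11) were the highest, and Mest (0.516, 0.503 to 0.529), Igfbp5 (0.524), Nrtn (0.538), Hotairm1 (0.564) and Phlda1 (0.616) the lowest. Wnt targets had 3 of 16 higher with Axin2 at 1.65-fold (1.51 to 1.81), Notch genes 4 of 11 and streak markers 4 of 7. Within the cluster marked by Pax1 and Meox2 (259 and 610 cells) Dll1 was still 1.79-fold (1.69 to 1.88) higher, Ptk7 and Arg1 1.64-fold, Axin2 1.76-fold (1.59 to 1.96) and T 1.52-fold, with 5 of 16 Wnt targets and 5 of 10 caudal markers higher. Hotairm1 (0.555), Mest (0.661) and Phlda1 (0.669) were lower in it. Over its cells of at most 1.5 times the median UMI count of their library (98 of G, 294 of R) Dll1 stayed at 1.62-fold (1.42 to 1.84), but the intervals of Axin2 (1.12, 0.865 to 1.45) and T (0.978, 0.745 to 1.28) held 1. There 2 of 13 Wnt targets were higher and 1 lower, and 2 of 10 caudal markers were higher. In the cluster led by Ripply2 and Mesp2 itself (226 and 114 cells), Hes7 (1.36-fold), Fgf8 (1.82-fold) and Axin2 (1.41-fold, 1.13 to 1.78) were higher, Mest (0.624) and Uncx (0.592) lower, and the somite list had 0 higher and 1 lower.

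How the 120 h cells differed from 96 h was asked for G and R apart, both against the same 96 h library. The 120 h cells were sorted on GFP, while no sort is described for the 96 h library. Time therefore cannot be told apart from sorting and handling in any of these ratios, those of the dissociation stress genes included. By CPM the median of all genes was shifted, to a log2 of 0.20 for G and 0.10 for R, and median-of-ratios scaling brought each to −0.02. Igfbp5 was 31.7-fold (24.6 to 41.6) higher in G and 85.9-fold (66.7 to 113) higher in R, from 1.08 CPM at 96 h. Posterior Hox genes, which set position along the axis, followed. Hoxa9 (ENSMUSG00000038227, chromosome 6, 52223100 to 52231089) was 28.2-fold (23.0 to 35.0) and 31.6-fold higher in G and R. Hoxd9 was 26.0-fold and 19.3-fold, Hoxc9 15.5-fold and 14.3-fold, and Hoxc6 8.01-fold and 7.35-fold. The somite transcription factor genes Tcf15 (8.27-fold and 10.9-fold) and Meox1 (6.46-fold and 8.51-fold) and the netrin gene Ntn1 (7.33-fold and 6.69-fold) completed the 8 highest of at least 50 CPM.

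Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772), a pluripotency factor, was the lowest by the same minimum, at 68.6 CPM at 96 h against 1.31 in G and 1.47 in R, 52.3-fold and 46.8-fold lower. The Nodal cofactor gene Foxh1 was 25.5-fold and 20.7-fold lower, the GDNF family receptor gene Gfra3 16.1-fold and 21.9-fold, and Sprr2a3 7.64-fold and 10.4-fold. Next came the tubulin regulator gene Stmn2 8.96-fold and 7.22-fold, Fgfbp3 7.70-fold and 7.02-fold, the early caudal gene Cdx1 5.40-fold and 6.50-fold, and Grsf1 4.82-fold and 5.58-fold. Of the canonical genes, Sox2 was 1.53-fold and 1.80-fold higher in G and R, Nodal 2.06-fold and 2.82-fold and Bmp4 1.44-fold and 1.37-fold. Cdh1 was at 0.391 and 0.274 of its 96 h level and T at 0.948 and 0.783.

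Hox paralogs 5 to 9 had 9 of 15 members higher and 3 lower in G and in R (medians 1.93 and 1.95), and of paralogs 10 to 13 all 4 measured were higher, although Hoxb13 in G turned to 0.425 with thinned cells. Hoxc10 had 0 UMIs at 96 h and was at least 218-fold higher in G and 228-fold in R, Hoxd10 at least 15.4-fold and 18.0-fold, and Hoxa10, with 3 UMIs at 96 h, 70.8-fold (24.0 to 346) and 83.0-fold (27.8 to 407). Somite markers had 10 of 11 higher (medians 2.69 and 3.09), with Uncx at 85.0-fold and 166-fold, while the retinoic acid synthesis gene Aldh1a2 was at 0.423 and 0.312. The pluripotency list had 5 of 7 lower in G and 6 of 7 in R (medians −1.99 and −2.47; Dppa5a 0.0924 and 0.0967). Neural markers had 5 of 8 higher and 1 lower in both (Sox1 4.51-fold and 6.61-fold, Pax6 2.80-fold and 3.36-fold, Irx3 2.71-fold and 2.94-fold; Nkx6-1 0.454 and 0.378).

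Among the pathways, Notch genes had 8 members higher in G and 5 in R, with Hey1 (4.78-fold and 4.27-fold), Nrarp (3.97-fold and 3.03-fold), Heyl (3.78-fold and 6.35-fold) and Hey2 (2.70-fold and 2.59-fold). BMP targets had 5 higher in each (Id2 2.46-fold and 2.72-fold, Msx2 2.64-fold and 2.52-fold), and matrix genes 6 and 4 (Fbn2 4.23-fold and 4.68-fold, Vcan 2.39-fold and 1.99-fold). Epithelial genes had 5 and 6 lower (Esrp1 0.176 and 0.237), and retinoic acid genes 5 and 4 (Crabp1 0.443 and 0.383), with 2 and 1 higher. The Nodal list had 4 lower in each (Lhx1 0.313 and 0.198), with 2 higher in G and 3 in R, among them Cer1 at 19.0-fold and 15.1-fold. Wnt targets were split, 5 higher and 2 lower in G and 3 each way in R, with Dkk1 (2.20-fold and 1.62-fold) and Ccnd1 (1.85-fold and 1.64-fold) higher and Cdx1 and Sp5 (0.467 and 0.354) lower. Their medians of 0.15 in G and −0.02 in R turned to −0.07 with median-of-ratios scaling and to 0.06 with the mean of per-cell CPM. The FGF list had 2 members higher in G, with a median of 0.23 that equals that of matched lists (percentile 51.7), and 1 higher and 1 lower in R, with a median of −0.23 (percentile 0.06). Of the stress genes 4 and 6 were higher (Jun 6.46-fold and 5.60-fold, Atf3 3.17-fold and 4.01-fold), and of the glycolysis genes 3 and 4 (Vegfa 2.72-fold and 2.64-fold, Gapdh 1.96-fold and 2.38-fold). The mesenchymal list had 3 of 12 higher in G (Pcdh8 3.36-fold) and 5 higher and 1 lower in R. The S phase list had no member beyond 1.5-fold, the G2/M list 1 in G. Among the rarer types, endothelial markers had 2 of 4 lower in G (median −0.59) and 4 of 6 higher in R (1.21; Cldn5 23.6-fold), endoderm markers 4 lower in G and 3 in R (Trh 0.0474 in G, Foxa2 2.40-fold in R), and the cranial list 3 higher in each, with 3 lower in G and 2 in R.

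**Figure D3:**
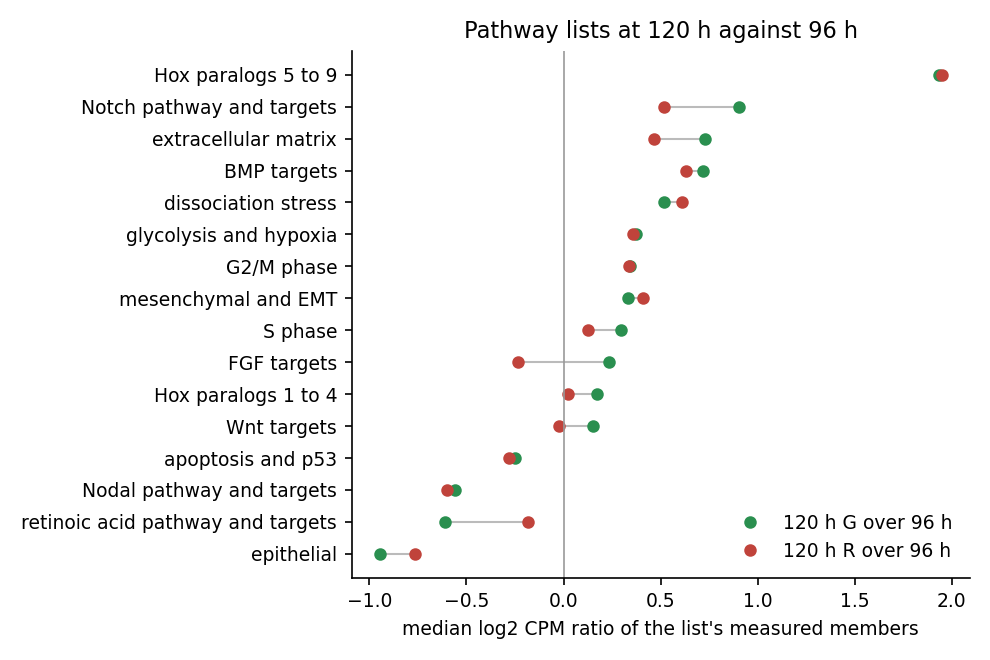
Median log2 CPM ratio to 96 h (horizontal axis) of the measured members of the pathway lists, G in green and R in red. Hox paralogs 10 to 13 (6.23 in G and 6.47 in R) are not drawn. Points are medians and carry no error bars. Hox paralogs 5 to 9 lay at 1.93 and 1.95; the Wnt medians of 0.15 and −0.02 turned sign under other scaling (−0.07 and 0.06), as did those of Hox paralogs 1 to 4 (0.17 and 0.02 to −0.04 and −0.10).

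What the gastruloid contained when the signal was recorded was asked within the 96 h library. PSM-like cells made up 56.0% (54.2 to 57.7) of it, NMP-like cells 36.0% (34.3 to 37.7) and endoderm-like cells 0.573%, with 7.33% unnamed. The PSM-like name depended on the clustering: its share was 0% in 4 of the alternatives and 33.2% and 33.4% in 2 others. Those 4 gave 22.2% to 44.5% of the 96 h cells the somite-like name. NMP-like cells were 15.4% at resolution 2, and endoderm-like cells fell from 18 to between 3 and 8 in 5 alternatives (resolution 0.5, no filter, thinned, Scrublet at 4 times the rate and without the genes that differed between G and R). T was 6.03-fold (5.72 to 6.37) higher in the NMP-like than in the PSM-like cells, Wnt3a 8.38-fold and Cdx4 8.15-fold. They are among the markers that gave the NMP-like cells their name, so their direction was set by the naming. Other Wnt targets split between the classes. Axin2 (133 against 81.9 CPM, 1.62-fold, 1.54 to 1.72), Notum (3.33-fold) and the receptor-removing gene Rnf43 (5.26-fold) were higher, and Lef1 (90.8 against 318 CPM, 0.286), Nkd1 (0.529) and Dkk1 (0.608) lower. Epithelial genes had 9 of 10 higher, with Cdh1 at 37.4 and 2.09 CPM (17.9-fold, 14.0 to 23.2), the claudin genes Cldn6 and Cldn7 at 65.5-fold and 27.7-fold and Epcam at 10.8-fold. Mesenchymal genes had 8 of 12 lower, with the fibronectin gene Fn1 at 54.2 and 384 CPM (0.141) and Snai1 at 0.146.

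Notch genes had 6 of 10 lower in the NMP-like cells (Lfng 0.106, Dll1 0.176, Notch1 0.356) and Hes1 3.57-fold higher. Lfng and Dll1 are among the markers that named the PSM-like cells, and Cyp26a1 and Fgf8 among those of the NMP-like cells. The direction of these marker genes was set by the naming. Anterior Hox genes were lower (7 of 12; Hoxd3 0.0577, Hoxd4 0.196) and Hox paralogs 5 to 9 mostly higher (8 of 14, with 4 lower; Hoxc8 11.1-fold, Hoxc9 8.46-fold, Hoxc6 7.48-fold). Aldh1a2 stood at 4.55 and 392 CPM (0.0116), while Cyp26a1, which degrades retinoic acid, was 9.51-fold higher. The glucose carrier genes Slc2a3 and Slc2a1 were 20.8-fold and 4.17-fold higher, the FGF targets split (Etv4 3.01-fold, Dusp6 0.396), and Sox2 was 10.3-fold and Fgf8 2.68-fold higher. Of the dissociation stress genes 5 of 10 were higher (median 0.68; Junb 2.72-fold, Ier3 2.59-fold) and of the p53 targets 5 of 10 (0.51; Pmaip1 4.799-fold, Cdkn1a 2.27-fold). S phase (median 0.13) and G2/M (−0.03) genes had no member beyond 1.5-fold.

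**Figure D4:**
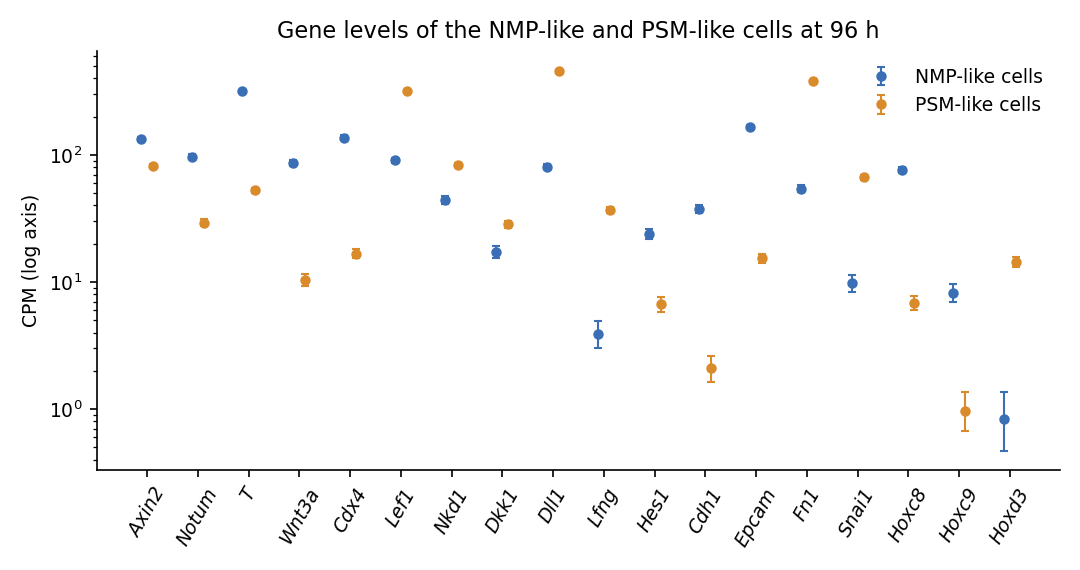
CPM (log axis) of 18 genes in NMP-like (1130 cells) and PSM-like (1757 cells) cells of the 96 h library; points are CPM of summed UMIs and bars 95% Poisson intervals. Cdh1 stood at 37.4 and 2.09 CPM and Lef1 at 90.8 and 318 CPM.

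UMIs of the iRFP reporter were counted in every 96 h cell, at a median of 139 per 10000 endogenous UMIs, so the top 25% and the bottom 25% of cells by this level (768 each, iRFP-high and iRFP-low) were compared, a split chosen after the values were seen. Free reporter RNA was not measured, so a low count does not show expression. What drives iRFP is not given in the sources used here. NMP-like cells made up 90.4% (88.1 to 92.4) of the iRFP-high and PSM-like cells 88.9% (86.5 to 91.1) of the iRFP-low cells. Caudal genes were higher in the iRFP-high cells, 10 of 10 (T 337 against 29.7 CPM, 11.4-fold, 9.37 to 13.9; Wnt3a 24.6-fold, Fgf17 24.4-fold, Cdx4 24.2-fold, Nkx1-2 18.4-fold), along with Ttyh1 (35.5-fold, 16.0 to 97.8), Skap1 (21.7-fold), Slc2a3 (19.96-fold) and Cdh1 (23.0-fold). Foxc2 was 76.2-fold, Aldh1a2 45.0-fold and Lhx1 33.1-fold lower, followed by Foxc1 (0.0412), Frzb (0.0429), Prrx2 (0.0473), Pcdh19 (0.0474) and Mesp1 (0.0480). Dissociation stress genes had 5 of 8 higher and 1 lower. Wnt targets had 9 of 14 higher, Axin2 by only 1.65-fold (1.43 to 1.91), Notum by 4.85-fold and Dkk1 by 2.81-fold, against Lef1 at 0.326.

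The recorder construct itself was 3.03-fold (2.98 to 3.07) higher in G than in R, which follows the labels of the sort, and 2.42-fold to 3.22-fold higher in each cluster compared. The iRFP reporter was 1.36-fold (1.35 to 1.36) higher in G, the rTTA transactivator 1.71-fold (1.67 to 1.75) and BFP 1.46-fold (1.404 to 1.518), while iCre had 0, 3 and 2 UMIs at 96 h, in G and in R.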

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

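Of the tests in this part, all were chosen after the result they measure was seen, except that of more Wnt target RNA in recorded somite-like cells, which was written before its value was computed.

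Dll1, Tbx6 and Axin2 drew attention because they lay on opposite sides of their 96 h level in the 120 h libraries. Dll1 was at 1.498 of its 96 h level in G and 0.941 (0.918 to 0.965) in R, Tbx6 at 1.18 and 0.829, and Axin2 at 1.05 and 0.743. Each library stands for its whole group, and whether G and R differ in their change from 96 h was not tested. The sides of Dll1 and Axin2 are also not firm: Dll1 in R came to 1.05 with the mean of per-cell CPM and 1.01 with thinned cells, and Axin2 in G to 0.902 with median-of-ratios scaling and 0.987 with thinned cells.

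Presomitic markers and Wnt targets were both higher in G than in R, with median log2 ratios of 0.51 and 0.28. For the Wnt targets, weighting the clusters of G as in R left 0.25 (percentile 100), which argues against the shares of the clusters as the whole cause. The weighting took whole clusters with their deep cells, so it cannot exclude a different mix of cells inside a cluster. Within NMP-like cells the Wnt median was 0.18 (percentile 99.9) and within PSM-like cells 0.03 (percentile 49.2). The Wnt list did not stand alone in the NMP-like cells. Presomitic (0.22, percentile 99.96) and S phase genes (0.10, percentile 99.8) were also higher, and somite (−0.38, percentile 0.02) and neural genes (−0.24, percentile 0.19) lower. Transcript length is argued against, since the median against genes of like exonic length was 0.23 (percentile 100). For the presomitic markers length is also argued against (0.51). The same weighting lowered their median from 0.51 to 0.18 (percentile 99.9), so most of their excess went with the mix of clusters, without showing which cluster carried it. These markers also named the PSM-like clusters and were not kept out of the clustering. The fall therefore cannot tell a difference in shares from a change of these genes in the cells, and it is not like that of the Wnt targets. Leaving out the deep cells of 2 clusters gave 0.41 for presomitic markers and 0.20 for Wnt targets. A difference in Wnt activity that outlasts the recording by a day stays open for the Wnt targets, as does any difference between the 2 sorts or library preparations, which coincide with the groups.

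Caudal genes such as T and Cdx2 were present in the somite-like cluster marked by Pax1 and Meox2, more so in G over all its cells. Free RNA in the droplets is argued against, because it would reach every cluster alike, while the caudal list was 3.57-fold (3.36 to 3.79) higher there than in the other somite-like cluster in G and 3.76-fold (3.28 to 4.32) in R. The gap was smaller in its cells that were not deep, which held 402 CPM of the caudal list in G and 364 in R. The other cluster held 202 and 133 CPM. Droplets with 2 cells cannot be told apart from single cells with both programmes: the deep cells of the cluster, 161 of 259 in G and 316 of 610 in R, held 2.01 times the caudal RNA of its other cells in G and 1.51 times in R, with higher Scrublet scores (medians 0.135 and 0.110 against 0.0545 and 0.0463) and far more iRFP (medians 91.0 and 43.9 per 10000 against 6.97 and 5.76, with 266 and 206 in NMP-like cells). The true doublet rate is not given in the sources used here, and the share removed was fixed by the setting. Recorded somite-like cells may keep more Wnt target RNA, but these values do not single it out. Among the cells that were not deep the Wnt list still had a median of 0.31 (percentile 98.7), with 2 of 13 higher and 1 lower. That median is the value of Wnt3a, with 20 UMIs in G and 25 in R (1.23, 0.649 to 2.31). Notch (0.40, percentile 99.99), glycolysis (0.27, percentile 99.7) and endoderm (0.92, percentile 99.7) genes were also raised there, and BMP targets (−0.36, percentile 0.14) were among those lowered. The excess of caudal genes in G was mostly gone in these cells, with a caudal list median of 0.17 (percentile 67.6), 2 of 10 higher and 0 lower. The intervals of T (0.978, 0.745 to 1.28), Cdx2 (1.09, 0.896 to 1.32) and Axin2 (1.12, 0.865 to 1.45) held 1, against Sp8 (2.05, 1.07 to 4.02) and Cdx4 (1.403, 1.06 to 1.85).

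Endoderm-like cells were found in R (31) and hardly in G (1). That the clustering missed them in G is argued against by the summed CPM of Sox17, Foxa1, Foxa2, Trh and Spink1 over all cells, which in G was 0.0967 (0.0794 to 0.117) of that in R, 130 UMIs against 582. A weaker recording system in these cells stays open as a candidate explanation. The 18 endoderm-like cells at 96 h (3 to 20 over the clusterings run) had less rTTA RNA per iRFP RNA than NMP-like cells (0.427, 0.358 to 0.505) and than PSM-like cells (0.620, 0.520 to 0.735). With the driver of iRFP unknown, that ratio does not show whether a cell with Wnt activity went unrecorded. Against PSM-like cells the ratio is low because iRFP was high: rTTA itself stood at 559 CPM in endoderm-like, 296 CPM in PSM-like and 1805 CPM in NMP-like cells, so less rTTA than in PSM-like cells was not seen. That the endoderm-like lineage had no Wnt activity at 96 h stays open and was not tested; of its 18 cells 10 were among the iRFP-high and 0 among the iRFP-low cells (median 351 per 10000, against 397 in NMP-like and 74.0 in PSM-like cells), but what drives iRFP is not given in the sources used here.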

How the results depend on the processing

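The counting intervals are narrow for abundant genes and wide below about 1 CPM, and with 1 library per group no alternative measures the spread between gastruloids or sorts. R has the fewest cells and the lowest depth, which limits its rare classes and weak genes. Reporter counting, leaving out 4 unnamed clusters, Scrublet at 4 times the rate, leaving out deep cells, clustering without G-to-R genes, and the iRFP splits were chosen after the data were seen. The cause was not tested for any of the changes given here, except that a higher minimum or threshold leaves fewer members to count by construction. Thinning can also leave fewer members, since it lowers the sums to which the UMI minimum applies. A list median or count that changed with thinning therefore does not show an effect of equal depth on the same members.

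A gene counts as turned here if its main interval excluded 1, and a list median if it lay outside the middle 95% of its matched lists; medians inside it that changed sign count as stayed or moved. With each cell thinned to 5000 UMIs these turned: G over R medians of endoderm (0.12) and intermediate mesoderm (0.18), the G over 96 h median of cardiac genes (1.36), Axin2 (0.987) and Hoxb13 (0.425), R over 96 h Dll1 (1.01), and the somite list within somite-like cells (−0.0490). A minimum of 200 UMIs took the endoderm median to 0.0029. With the mean of per-cell CPM, Ntn1 G over R (0.964) and Dll1 R over 96 h (1.05) turned. Without deep cells Fgf17 (0.993) and Nkx1-2 (0.996) G over R, and the streak median (0.0203) and Dll1 (1.05) R over 96 h turned. With median-of-ratios scaling these turned: Axin2 (0.902), Cdx2 (0.999), Id1 (0.953), Spred2 (0.952) and Hoxb1 (0.921) for G over 96 h, and Dll3 (0.980), Fgf8 (0.995), Mcm6 (0.982), Mcm2 (0.984), Mcm4 (0.974) and Snai1 (0.991) for R over 96 h.

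With each library clustered alone the PSM-like share ratio turned to 0.894 and the somite list within PSM-like cells to −0.83; that list also turned with no cell filter (−0.15), the stricter filter (−0.0595), clustering without G-to-R genes (−0.15) and Scrublet at 4 times the rate (−0.15). The somite-like share ratio moved from 0.496 to 0.692 with each library alone, 0.550 with no filter, 0.693 with doublets kept, 0.736 thinned and 0.658 without G-to-R genes; it was below 1 in all clusterings run. Endoderm-like cells made up 2.72% of R with each library alone. The PSM-like ratio moved to 1.54 thinned and the NMP-like ratio to 1.01 without deep cells.

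Of the list members, 5 were higher in G than in R, and 1 with median-of-ratios scaling, 2 without deep cells and 1 at 2-fold; 34 were lower, and 17 thinned, 14 at 200 UMIs and 17 at 2-fold. For G over 96 h the 48 lower became 27 at 200 UMIs and the 84 higher 53 at 2-fold, and for R over 96 h the 45 lower became 27 at 2-fold. Median-of-ratios scaling took the split of higher and lower members from 84 and 48 to 65 and 60 for G over 96 h and from 84 and 45 to 71 and 49 for R over 96 h. Within NMP-like cells 4 were lower and 8 with 3000 variable genes. Within PSM-like cells 2 were higher, and 4 without cell cycle genes, 6 with each library alone, 4 with the stricter filter and 1 thinned; 1 was lower, and 3 at resolution 0.5, 0 at resolution 2, 4 with 3000 genes, 2 without cell cycle genes, 5 with each library alone, 3 with no filter, 2 with the stricter filter, 0 thinned, 2 without G-to-R genes and 2 with Scrublet at 4 times the rate. Within somite-like cells 12 were lower, and 21 with each library alone and 21 with doublets kept.

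Of 6169 values of single genes under an alternative 5395 stayed within their interval, 755 moved with the same direction and 19 turned. Of 1305 list medians 988 stayed, 306 moved and 11 turned by that rule, and of 2730 counts of list members 2451 stayed within 1.5 times and 279 did not. These totals pool mild and strong alternatives. With doublets kept 617 of 617 genes stayed. With median-of-ratios scaling only 345 of 617 genes and 32 of 97 list medians did, and with thinned cells 407 of 616 and 54 of 109. The contrast of NMP-like with PSM-like cells at 96 h gave no value at resolution 2, without cell cycle genes, with the stricter filter and with doublets kept, where no 96 h cluster took the PSM-like name and part of the 96 h cells took the somite-like name. The planned iRFP splits, cells with at least 1 or at least 2 UMIs against cells with none, were not run, since no kept cell had 0 UMIs.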

Other observations

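The tests of this part, and the genes named in it, were chosen after the values were seen. The unnamed 120 h cluster led by Mesp1, Bmp2, Frzb and Lhx1 had 4 presomitic markers (Tbx6, Dll1, Dll3 and Cited1), none of them among its 10 leading genes, which hold Mesp1 and Lhx1 of the streak list. It held 23.5% of G against 14.96% of R (1.57, 1.39 to 1.77). Within it, 2 of 15 Wnt targets were higher in G and none lower, with a median log2 ratio of 0.22 (percentile 100) and Axin2 at 1.16 (1.03 to 1.32). Fasn (1.34-fold), Cad (1.36-fold), Hoxb9 (1.30-fold), Peg3 (1.30-fold) and Fn1 (1.29-fold) were higher there, and Sox2 (0.509), Ybx3 (0.691) and Lars2 (0.742) lower.

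Inside the NMP-like cells of 96 h the iRFP level went with a few Wnt targets, while most caudal markers were not higher with it. What drives iRFP is not given in the sources used here, so the split is not a measure of Wnt activity. Between its top and bottom 25% (283 cells each), Notum (1.56, 1.36 to 1.80), T (1.51), which is also a caudal marker, and Axin2 (1.20, 1.07 to 1.34) were higher, in a Wnt list with 2 of 14 members higher and a median of 0.06 (percentile 89.4), while the caudal list had a median of −0.26 (percentile 0) and Hox paralogs 5 to 9 of −0.38 (Hoxa7 0.532, Hoxc5 0.579), with Mixl1 at 2.87-fold and Hes3 at 0.0621. Inside the PSM-like cells (440 each) the split separated caudal from somite markers: caudal genes were higher, 10 of 10 with a median of 2.48 (Fgf17 22.7-fold, Cdx4 17.2-fold, Wnt3a 13.1-fold, T 5.25-fold), somite genes lower, 7 of 7 with a median of −2.74, and 8 of 14 Wnt targets higher (Dkk1 14.7-fold, Notum 2.34-fold, Sp5 1.76-fold, Axin2 1.31-fold). Leaving Cdx4, T, Wnt3a and Sp8, which are also caudal markers, out of the Wnt list gave 0.13 for NMP-like over PSM-like cells at 96 h (12 genes, percentile 91.0) and 0.46 for the iRFP-high over the iRFP-low cells (10 genes, percentile 99.9).

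The interval of G over R lay above 1 in each of 6 clusters compared for 40 genes and below 1 in each for 29, at any size of the ratio. The higher genes include Dll1 (1.15 to 1.79 across the clusters), Hes7 (1.07 to 1.36), Hoxb1 (1.11 to 1.253), Ctnnb1 (1.16 to 1.33), Cad (1.247 to 1.473), Nes (1.32 to 1.76) and Cdkn1a (1.17 to 1.42), and the lower ones Ybx3 (0.659 to 0.804), Hnrnpa0 (0.703 to 0.764), Lars2 (0.563 to 0.889), Ier5l (0.369 to 0.622) and Atp5k (0.732 to 0.803). Length differed between these sets, with median exonic lengths of 5384.5 and 2098 bases against 4549 for all 12747 genes. Across deciles of length the median log2 G over R went from −0.03 (median length 1377) to 0.15 (12742). A difference in library quality or RNA integrity between G and R could therefore account for part of the smaller ratios, though the Wnt median against genes of like length stayed at 0.23. No test here separates this from a biological cause for single genes.

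The rTTA transactivator was 2.52-fold (2.36 to 2.69) higher in G in the somite-like cluster marked by Pax1 and Meox2 and 3.99-fold (2.62 to 6.38) in the other somite-like cluster, against 1.27-fold to 1.61-fold in the other 5 clusters compared. In the former, deep cells, which may be doublets (caudal ratio to the others 2.01 in G and 1.51 in R), had more iRFP (medians 91.0 against 6.97 per 10000 in G and 43.9 against 5.76 in R). The recorder construct stood at 743 CPM at 96 h, 2059 in G and 681 in R.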
